A study of Arabidopsis thaliana with 27 samples.

How the data were processed

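Gene expression was measured in Arabidopsis thaliana on 27 spotted cDNA arrays with 2 dyes, which carry 2560 spots. Per the labels' protocols, treated RNA was labelled with Cy5 and RNA of untreated plants grown in parallel with Cy3, without dye swaps. A dye effect of a gene that is the same on every array therefore cancels between agents and between times, but not in comparisons with untreated plants. The untreated plants are not described as sprayed with a mock solution, and sprayed plants were kept at high humidity, per the labels. The labels name the tissue both as leaves and as the plant without root. The deposited values are log ratios, taken here as log2 of treated over untreated. The logarithm's base, the background correction, any spot filter and any normalization by the authors are not given in the sources used here. A base of 10 was excluded by the range of the values (-10.6 to 10.9), and a natural logarithm was not excluded. Per the labels, slides were scanned with a ScanArray Lite scanner and spots were summarised by the median of their pixels.

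Each sample's agent, dose and time were taken from its title. The jasmonate samples are titled JA and their source names say MeJA, which is the name used here. Repeat arrays of 3 conditions shared their RNA per the labels and were averaged to 1 sample. At most 1 spot held identical values on both arrays of a pair, so none was a copy. All columns were matched to samples, and 1 closing line of the table without values was dropped. Missing spots stayed missing. There are no intensities, so signal over background is unknown, and missing values may fall more often on dim spots.

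Spots were named through the platform's annotation, with symbols updated by gene number from the RefSeq table of assembly TAIR10.1, in which 415 of 416 genes matched. One gene symbol was given for 884 spots, several for none, and no name for 1676 spots, which are unnamed here. TUA5 has 54 spots and each of the other 415 genes has 2. Spots of the same gene correlated within arrays with a median r of 0.969, against -0.0045 for shuffled pairs. No genome build is stated for the array, so no coordinates are given.

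The rule set before the data were examined was to keep the deposited centring if every array's median lay within 0.2 of 0, and otherwise to centre each array on its median. On 23 arrays the median lay outside, so arrays were median-centred. Spots of a gene were averaged. A gene was tested if it had values in at least 20 of 24 conditions and in at least 3 of the 4 times of each agent, which left 180 of 416 genes, 137 of them complete. R 4.3.3 and limma 3.58.1 were used. The additive model had a mean per agent and terms for time that sum to 0. Each gene was fitted by least squares on its measured conditions and its variance moderated by limma's empirical Bayes step (prior 8.16 degrees of freedom, 15 residual degrees of freedom for complete genes). P-values are two-sided and Benjamini-Hochberg adjusted over the genes of each comparison, with a threshold of 0.05. The untreated RNA is the reference on each array, and its own spread was not estimated. P-values measure only the spread over agents and times that the terms of the model leave, which may be partly technical. That spread includes the untreated RNA's if each array had its own, and leaves it out if the RNA was shared, which is not stated. Late (10 and 24 h) against early (2 and 5 h) was tested in a model with a mean per agent and phase. Gene lists were tested with camera at a preset correlation of 0.01, with a correlation estimated from the residuals, and with fry on complete genes. Of 260 genes on lists fixed before, 13 were on the array and 5 were tested (KIN2, COR15A, COR47, EIN3 and PYK10). Further lists (class III peroxidases, UDP-glycosyltransferases, ER bodies and associated lectins, berberine bridge enzyme-like oxidases, EF-hand proteins, amino acid catabolism, NB-ARC and TIR proteins, alkenal reductases) were drawn up after the gene names on the array were seen.

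Genes were named by a rule set at the same time. Per agent these are the 10 highest and 10 lowest means among genes past the threshold with 1 sign at all 4 times, plus genes of the fixed lists that passed. Per contrast and for time these are the 5 highest and 5 lowest. The markers PR1, PR2, PR5, PDF1.2, PR3, PR4, VSP2, LOX2 and the reference genes were to be given in any case. On simulated data with the real pattern of missing values in 180 genes, the comparison of ET with untreated recovered 20 of 20 genes changed by a log2 of 2, 20 of 20 changed by 1 and 6 of 20 changed by 0.5, and called 3 of 120 unchanged genes. For MeJA against ET these were 20, 13 and 1 of 20, with 0 unchanged genes called.

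Alternatives were other centrings and scalings, other filters, other treatments of the repeat arrays including the replicate number as a block, the doubtful INA label, the time term, each time left out, the conditions compared alone, the technical spread, trended and robust moderation, a minimum fold of 1.5, single spots and another definition of phase. Centring on TUA5 and leaving out the BABA arrays were added after seeing the data. The replicate numbers mark repeat arrays of the same RNA and pair no samples across conditions. Comparisons with untreated plants have no group of untreated arrays, so splits of samples were drawn only for comparisons between agents and between phases.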

Results

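The series measured how the transcripts of Arabidopsis thaliana plants (ecotype Columbia) differed from those of untreated plants after spraying with 6 defence-related agents. The agents were 5 mM SA (salicylic acid, a plant defence hormone), 1 mM INA and 0.5 mM BTH (synthetic activators used as functional analogs of SA), 10 mM BABA (the amino acid beta-aminobutyric acid, used as a resistance-priming agent), 1 mM ET (ethephon, which releases ethylene) and 0.1 mM MeJA (methyl jasmonate). Plants were harvested 2, 5, 10 and 24 h after spraying, which gives 24 conditions on 27 arrays. Each array compared treated RNA (Cy5) with RNA of untreated plants (Cy3) on a small spotted cDNA array of genes selected for a possible link to stress. The dyes were not swapped and no mock spray is described. Values against untreated plants may therefore hold effects of dye, spraying or humidity beside those of the agent. There were 2 arrays for INA at 10 h, INA at 24 h and BTH at 5 h, and 1 array for each of the other 21 conditions. The labels say that plants of replicate experiments were pooled before RNA extraction and that repeat arrays used the same RNA, so each condition counts as 1 sample. The tests below therefore ask whether the mean over the 4 times of an agent differed from 0. Every mean over times carries the standard error (SE) of that fit. The terms for time take up time courses common to all agents, so a call does not show that a change was held over the 4 times. Values are log2 ratios of treated over untreated after each array was centred on its median. The base of the deposited logarithm is not stated and was taken as 2, so folds rest on that reading.

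The arrays held between 1204 and 2358 spots with a value, and the number of arrays limits the precision. Of 416 named genes, 180 had values in enough conditions to be tested. The median of the deposited values ran from -0.76 on the BABA 2 h array to 1.49 on the first INA 10 h array. Arrays of the same RNA differed in this median as well, with 1.49 and 0.26 at INA 10 h, -0.65 and 0.35 at INA 24 h, and -0.50 and 0.37 at BTH 5 h. Across spots, the repeat arrays correlated with r = 0.931 at INA 10 h, 0.886 at INA 24 h and 0.838 at BTH 5 h. TUA5, an alpha-tubulin gene spotted 54 times, lay below the array median on 25 of the 27 arrays. Its mean was -1.16 under SA, -0.88 under INA, -1.36 under BTH and -0.92 under MeJA, all past the threshold, and -0.26 under BABA and -0.37 under ET, which were not (SE 0.17 for each). When arrays were centred on TUA5, a choice made after seeing the data, the median of all tested genes rose to 1.15 under SA, 0.90 under INA, 1.42 under BTH, 0.27 under BABA, 0.42 under ET and 0.82 under MeJA. Without centring it stood at 0.85, 0.69, 0.35, 0.38, 0.77 and 0.25 in the same order. "Higher" and "lower" below are therefore relative to the median spot of the array.

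SA was compared with untreated plants to show which transcripts differed after spraying with the hormone. The highest means belonged to AT5G51830, a pfkB-type carbohydrate kinase gene, at 3.04 ± 0.34 (8.24-fold), and to AT3G15450 at 3.01 ± 0.38. AT5G05600, an oxygenase gene of the jasmonate-oxidase family, reached 2.84 ± 0.26. The neighbouring berberine bridge enzyme-like genes AT4G20830 and AT4G20840 rose to 2.78 ± 0.28 and 2.84 ± 0.27, and the membrane protein gene AT2G18690 to 2.71 ± 0.25. The peroxidase gene AT5G64120 rose to 2.46 ± 0.26, the EF-hand gene AT4G27280 to 2.41 ± 0.32, AT5G64250 to 2.38 ± 0.25 and AT2G15960 to 2.37 ± 0.26. At the other end, the GDSL lipase gene AT1G29660 lay at -3.16 ± 0.25 and FUG1, a chloroplast translation initiation factor, at -2.65 ± 0.25. The NRT1/PTR-family transporter genes AT3G21670 and AT2G26690 lay at -2.18 ± 0.37 and -1.92 ± 0.18. DRT100 (-2.24), AT4G18030 (-2.15), the glutaredoxin gene AT1G64500 (-1.88), AT4G14360 (-1.84), the TIR-type resistance gene homolog AT3G44670 (-1.84) and AT5G44020 (-1.67) were lower too. Each of these 20 genes had 1 sign at all 4 times, and the largest adjusted p among them was 2.1e-05 (limma). In all, 131 of 180 genes passed the threshold, 67 higher and 64 lower. The split was 97 higher and 14 lower in the deposited values, and 125 and 11 after centring on TUA5.

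INA, set against untreated plants in the same way, gave AT5G64120 the highest mean. AT5G64120 rose to 2.88 ± 0.26 (7.37-fold), AT4G20840 to 2.84 ± 0.27, AT4G20830 to 2.74 ± 0.28, AT5G05600 to 2.45 ± 0.26 and AT2G39210, a major facilitator family gene, to 2.45 ± 0.25. AT5G51830 (2.31), AT2G18690 (1.90), AT5G35735 (1.69), YLS5 (1.61) and AT4G38550 (1.45) were also higher. AT3G21670 was lowest at -2.93 ± 0.37, followed by AT1G29660 at -2.78 ± 0.25 and AT2G26690 at -2.26 ± 0.18. The thionin gene AT1G66100 (-1.91), AT1G64500 (-1.91), the leucine-rich repeat gene AT3G20820 (-1.80), the remorin gene AT2G45820 (-1.79), AT4G18030 (-1.76), FUG1 (-1.68) and the TRAF-like gene AT3G28220 (-1.64) were lower. The largest adjusted p of these 20 genes was 0.00013. The test called 59 genes higher and 49 lower, against 86 and 15 in the deposited values and 115 and 14 after centring on TUA5. The source name of the first INA 10 h array says 2 h, while its title and protocols say 10 h. That array correlated with the second INA 10 h array at 0.931 and with the INA 2 h array at 0.779.

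Under BTH, AT3G29240 rose to 3.28 ± 0.29 (9.73-fold), AT2G25510 to 2.32 ± 0.25, AT2G18690 to 2.15 ± 0.25 and AT2G41410, a calmodulin-like gene, to 2.13 ± 0.20. PPDK, the pyruvate orthophosphate dikinase gene, rose to 2.03 ± 0.24 and AT5G64120 to 2.00 ± 0.26. AT4G27450 (1.96), ECS1 (1.89), AT5G51830 (1.77) and AT5G48540 (1.76) were higher as well. The beta-glucosidase gene BGLU44 was lowest at -3.42 ± 0.28, and COR47 lay at -3.38 ± 0.22. FUG1 (-2.84), the universal stress protein-like gene AT3G62550 (-2.75), AT3G28220 (-2.43), COR15A (-2.29), the oxygenase gene AT2G25450 (-2.06), KIN2 (-2.05), the resistance gene homolog AT1G61180 (-2.02) and the jacalin lectin gene AT1G52000 (-1.98) were also lower. EIN3, a transcription factor of ethylene signalling, lay at -0.83 ± 0.18 with an adjusted p of 0.0003. It turned to 0.54 when arrays were centred on TUA5, which passed the threshold as a higher call (adjusted p = 0.023). The largest adjusted p of the other 20 genes was 9.7e-05. BTH had 57 genes higher and 51 lower, against 60 and 27 in the deposited values and 145 and 9 after centring on TUA5.

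BABA gave the highest mean among the genes named for the 6 agents, AT2G18690 at 4.74 ± 0.25 (26.8-fold). AT2G39210 followed at 3.702 ± 0.25, AT5G64120 at 3.63 ± 0.26, AT5G35735 at 3.33 ± 0.25 and AT4G20840 at 2.96 ± 0.27. YLS5 (2.83), AT4G38550 (2.64), AT4G20830 (2.49), AT4G27280 (2.19) and AT2G41410 (2.01) were higher too. AT3G21670 lay at -4.09 ± 0.37 (17.0-fold lower), COR15A at -3.49 ± 0.36, AT3G28220 at -3.21 ± 0.32, AT1G29660 at -3.09 ± 0.25 and AT1G66100 at -2.89 ± 0.36. AT2G45820 (-2.10), AT1G52000 (-2.06), FUG1 (-2.05), AT1G73390 (-2.02) and AT2G26690 (-1.91) were lower, and the largest adjusted p of the 20 genes was 2.2e-06. There were 61 genes higher and 59 lower, against 69 and 36 in the deposited values and 70 and 43 after centring on TUA5. The BABA arrays had between 1346 and 1569 spots with a value, and the array at 10 h had the widest spread of deposited values of all arrays (SD 1.96).

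Under ET, AT5G64120 rose to 3.47 ± 0.26 (11.1-fold), AT4G36850 to 2.72 ± 0.33, AT5G05600 to 2.64 ± 0.26, PPDK to 2.62 ± 0.24 and AT2G39980 to 2.59 ± 0.20. AT2G18690 (2.58), FDH (formate dehydrogenase, 2.48), AT5G14120 (2.35), AT2G39210 (2.15) and AT2G41410 (2.04) rose as well. COR15A lay at -4.61 ± 0.36 (24.4-fold lower), KIN2 at -4.38 ± 0.30 (20.8-fold lower) and COR47 at -2.72 ± 0.22. AT3G62550 (-2.21), AT3G28220 (-2.04), CCL (-1.90), BGLU44 (-1.81), AT1G29660 (-1.80), AT2G45820 (-1.62) and FUG1 (-1.59) were lower, and the largest adjusted p of the 20 genes was 1.6e-05. The threshold was passed by 58 genes higher and 39 lower, against 90 and 11 in the deposited values and 68 and 18 after centring on TUA5. One protocol field of the ET 10 h array says 5 h, and its title and source name say 10 h.

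Under MeJA, AT5G05600 rose to 3.62 ± 0.26 (12.3-fold), AT3G28220 to 3.12 ± 0.32, the methyltransferase gene FAMT to 2.75 ± 0.25, AT1G52000 to 2.59 ± 0.26 and AT1G54010 to 2.54 ± 0.23. PPDK (2.30), AT5G14120 (1.94), AT2G41410 (1.82), AT1G66100 (1.67) and AT1G62660 (1.60) were higher. COR15A lay at -3.77 ± 0.36, COR47 at -3.03 ± 0.22, AT3G62550 at -2.97 ± 0.35 and KIN2 at -2.30 ± 0.30. AT4G38550 (-1.89), AT4G05150 (-1.70), RD2 (-1.48), DRT100 (-1.43), ECS1 (-1.33) and AT1G29660 (-1.32) were lower, and the largest adjusted p of the 20 genes was 0.00058. PYK10, the main beta-glucosidase of ER bodies and on the fixed list of root, seed and flower markers, rose under MeJA to 1.31 ± 0.36 and was lower under SA (-1.20), INA (-1.19) and BTH (-1.40). After centring on TUA5 the PYK10 means were 2.17 under MeJA, still past the threshold, and -0.11, -0.31 and -0.02 under SA, INA and BTH, no longer past it. EIN3 lay at -0.51 ± 0.18 under MeJA, which turned to 0.35 after centring on TUA5 (adjusted p = 0.151). MeJA had 40 genes higher and 43 lower, against 44 and 16 in the deposited values and 118 and 9 after centring on TUA5, when 127 genes passed in place of 83.

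**Figure D1:**
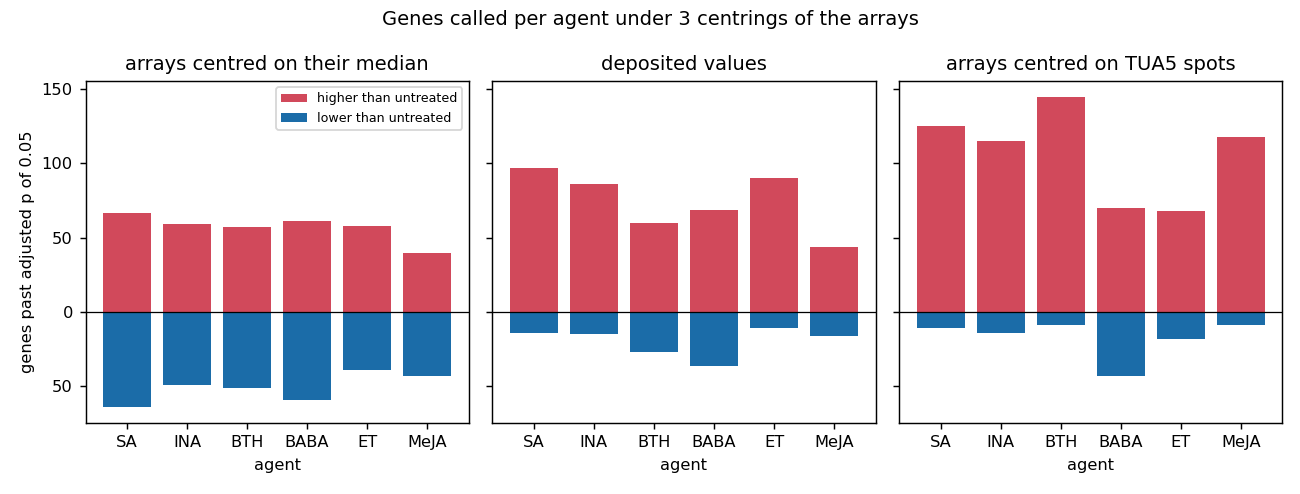
Number of genes past an adjusted p of 0.05 for each agent (x axis), with genes higher than untreated above 0 and genes lower below 0 (y axis, genes), for arrays centred on their median, for the deposited values and for arrays centred on their TUA5 spots. Under SA the split goes from 67 higher and 64 lower to 97 and 14 and to 125 and 11.

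Of the gene lists fixed before the data were examined, the list for dehydration, cold and ABA was the only one with at least 3 tested genes. Its 3 tested members, KIN2, COR15A and COR47, encode proteins that accumulate in cold and drought. All 3 fell under ET, MeJA, BTH and BABA, with 3 calls adjusted over the list alone for each of these agents. Under BABA the means were -1.30 ± 0.30 for KIN2 and -0.92 ± 0.22 for COR47, and the COR47 call was lost in the deposited values (-0.55). Under SA, COR15A (-1.06 ± 0.36) and COR47 (-0.82 ± 0.22) passed and KIN2 had a mean of -0.24 ± 0.30. COR15A and COR47 under SA turned to 0.03 and 0.27 after centring on TUA5, and neither then passed. Under INA, COR15A passed (-1.27 ± 0.36), while COR47 had -0.37 ± 0.22 and KIN2 -0.03 ± 0.30. After centring on TUA5 the COR15A mean under INA was -0.40 and did not pass. Calls adjusted over the list alone were 2 under SA and 1 under INA. Against the other genes, the list was lower under ET (camera, adjusted p = 4.5e-07), MeJA (adjusted p = 2.1e-05) and BTH (adjusted p = 0.00091). These calls held with an estimated correlation, at adjusted p = 0.00013, 0.0013 and 0.012. BABA gave an adjusted p of 0.097, SA 0.45 and INA 0.47. A test of the list against 0 (fry) gave adjusted p = 4.9e-06 for BABA, 0.017 for SA and 0.067 for INA. COR15A and KIN2 each have a close homolog on the array (COR15B and KIN1), and cross-hybridisation between such cDNAs was not assessed.

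The genes of the other fixed lists were few on this array. The markers PR1, PR2, PR5, PR3, PR4, VSP2 and LOX2 and the 6 reference genes were not among the named spots and were not analysed here. PDF1.2, a plant defensin gene of the ethylene and jasmonate branch, had too few values for the test. Under ET its ratio was 0.28 at 2 h, 2.78 at 5 h, 3.45 at 10 h and 2.57 at 24 h. It was 1.54, 2.44 and 2.08 at 5, 10 and 24 h of INA, 2.60 and 4.49 at 10 and 24 h of BABA, and 0.57 and 2.94 at 5 and 10 h of MeJA. BTH gave -0.13 at 5 h. SA gave no value at any time. STZ, a zinc finger gene of general stress signalling, was also untested, with 4.0015 and 2.70 at 2 and 5 h of SA and 2.06, 3.53 and 2.45 at 2, 5 and 10 h of BABA.

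**Figure D2:**
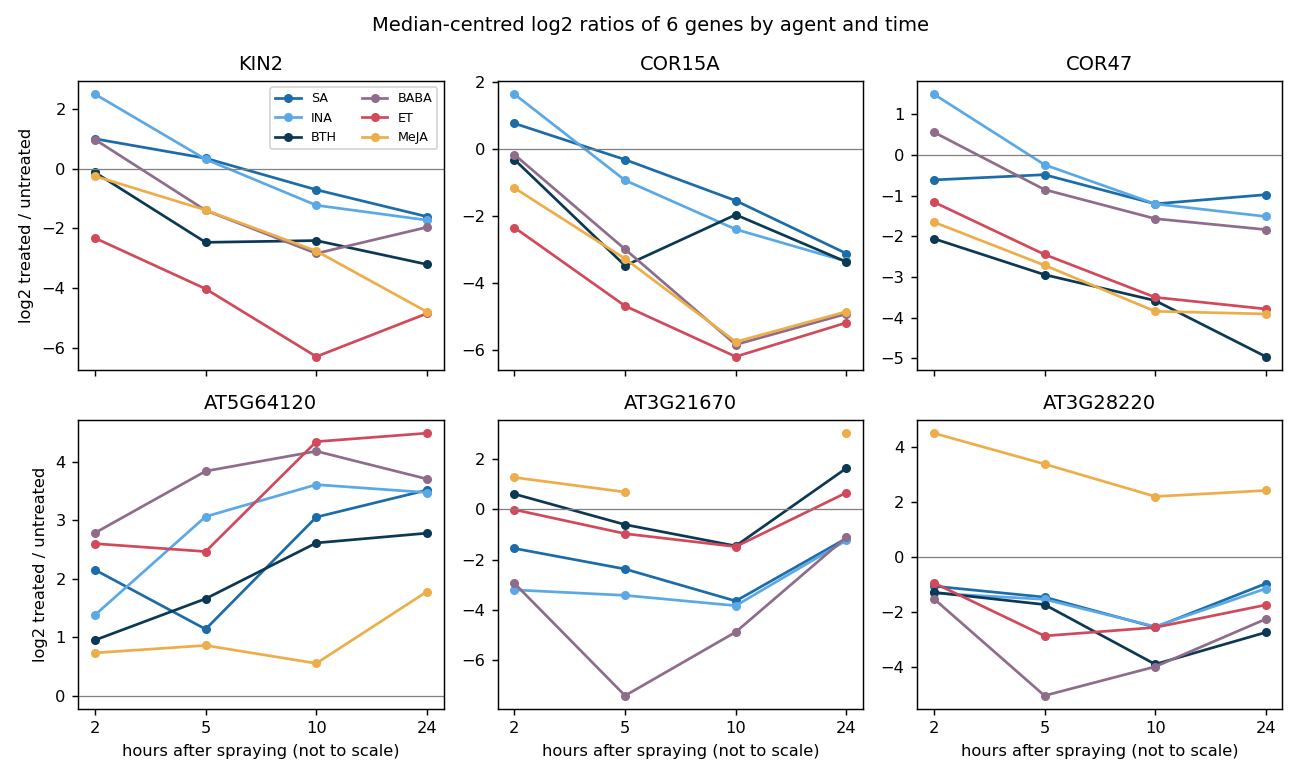
Median-centred log2 ratio of treated over untreated (y axis) of 6 genes at 2, 5, 10 and 24 h after spraying (x axis, evenly spaced), with 1 point per condition and 1 line per agent. KIN2 reaches -6.30 at 10 h of ET, and AT3G28220 lies above 0 at all 4 times of MeJA and below 0 at all times of the other agents.

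SA was then compared with its functional analogs INA and BTH at the same times. The doses differed (5, 1 and 0.5 mM), so the comparison is of these treatments and not of equal amounts. INA and SA differed in 12 of 180 genes, 5 higher and 7 lower under INA. AT4G27280 differed by -2.08 ± 0.45 (2.41 under SA), AT5G64250 by -1.84 ± 0.35, AT4G36850 by -1.67 ± 0.47, ALDH7B4 by -1.54 ± 0.38 and AT1G66760, a MATE-type transporter gene, by -1.52 ± 0.30. AT3G28940 (1.29 ± 0.30), DRT100 (1.27 ± 0.35), AT5G61590 (1.09 ± 0.22), AT1G75800 (0.92 ± 0.27) and AT1G23130 (0.90 ± 0.27) were higher under INA, and the largest adjusted p of the 10 genes was 0.049. The median half-width of the 95% interval of a difference, not adjusted for the number of genes, was 0.62. The threshold on adjusted p asks for more, and the smallest difference called was 0.90. AT3G15450, at -1.50 ± 0.53, was not called (limma, adjusted p = 0.082). So differences well above 0.62 could go undetected, and 44 genes had an unadjusted p under 0.05 (limma). With gene-level tests the count of 12 ranged from 0 to 26 under other settings, with 19 genes without the 2 h conditions, 0 without 5 h, 4 without 10 h and 7 without the repeat arrays numbered 2. In the deposited values the split was 0 higher and 5 lower, and after centring on TUA5 it was 0 and 6.

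BTH and SA differed in 73 genes, 35 higher and 38 lower under BTH. AT3G62550 differed by -3.21 ± 0.49, AT2G15960 by -2.97 ± 0.36, AT5G35735 by -2.59 ± 0.39, COR47 by -2.56 ± 0.31 and BGLU44 by -2.50 ± 0.40. AT1G64500 was higher by 2.78 ± 0.41 (0.90 under BTH and -1.88 under SA), AT3G21670 by 2.23 ± 0.53, AT1G66180 by 2.09 ± 0.25, AT5G44020 by 2.09 ± 0.33 and DRT100 by 1.89 ± 0.35, with adjusted p up to 0.0016. The split was 7 higher and 41 lower in the deposited values, 38 and 19 after centring on TUA5, and 36 and 26 after quantile normalization. BTH and INA differed in 61 genes, 32 higher and 29 lower under BTH. AT3G62550 (-3.77 ± 0.54), BGLU44 (-3.07 ± 0.40), CCL (-3.05 ± 0.44), COR47 (-3.02 ± 0.31) and AT5G35735 (-2.19 ± 0.36) were lower under BTH. AT3G21670 (2.97 ± 0.53), AT1G64500 (2.81 ± 0.41), AT3G29240 (2.09 ± 0.42), AT4G27450 (2.07 ± 0.35) and AT2G26690 (2.02 ± 0.26) were higher. Here the split was 7 and 19 in the deposited values and 50 and 10 after centring on TUA5, and 39 genes passed without the 2 h conditions.

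**Figure D3:**
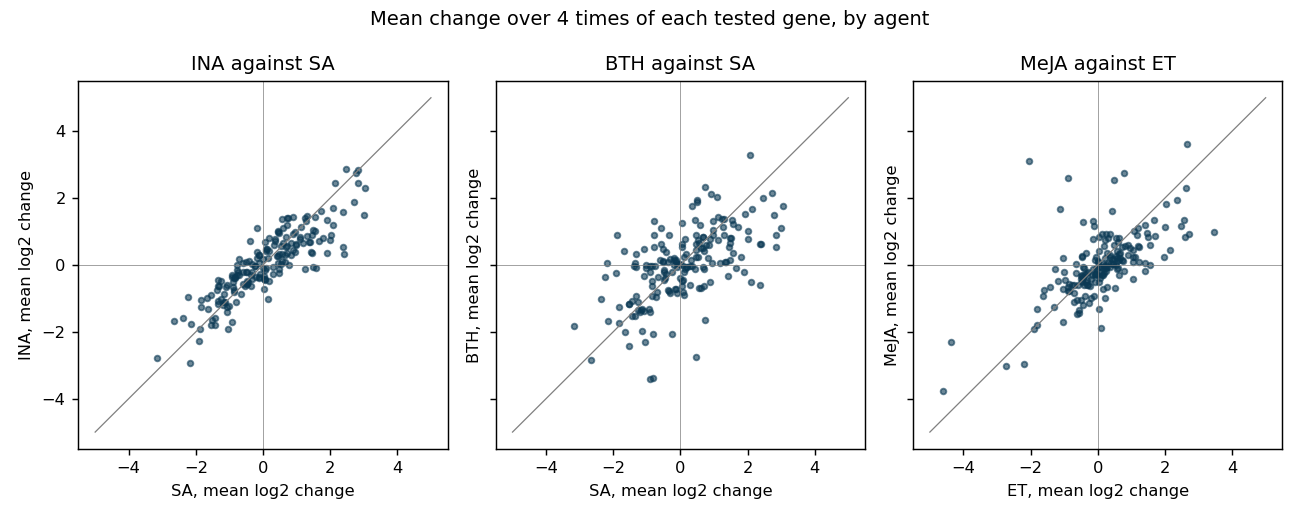
Mean log2 change over 4 times of each of the 180 tested genes under INA against SA, BTH against SA and MeJA against ET, with 1 point per gene and the line of equal change. The means correlate more closely between INA and SA (r = 0.871) than between BTH and SA (r = 0.600) or MeJA and ET (r = 0.641).

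Across the 180 genes, which are not independent replicates, the means correlated at r = 0.871 between SA and INA (Spearman 0.876), 0.851 between INA and BABA and 0.723 between SA and BABA. BTH and ET correlated at 0.752, BTH and SA at 0.600 and ET and MeJA at 0.641. MeJA correlated with SA at 0.213, with INA at 0.124 and with BABA at 0.153. Whether the untreated RNA was shared between arrays is not stated. In a simulation of unchanged agents against 1 shared reference, r was near 0.499 and the covariance near 0.051 for SA and INA. The observed covariance was 1.096. The reference and each agent were drawn with equal variance, which fixed the simulated r in advance. That variance came from residuals after the time terms, which take up deviations common to all agents at a time. The simulated covariances therefore set no bound on what a shared reference or a common dye offset could give. For INA and BABA and for SA and BABA the simulated r was 0.505 and 0.503, with observed covariances of 1.219 and 1.247 against 0.0517 and 0.0514. The simulated r was 0.498 for BTH and SA, 0.4995 for BTH and ET and 0.505 for ET and MeJA, and 0.494, 0.501 and 0.488 for MeJA with SA, INA and BABA, whose observed r lay below it. The observed covariances of these 6 pairs were 0.808, 0.914, 0.709, 0.261, 0.127 and 0.214, against simulated values between 0.0497 and 0.0516. SA and INA shared 47 genes called higher and 45 called lower, where independent lists would share 21.96 and 17.42. BTH and ET shared 40 and 28, where independent lists would share 18.4 and 11.1. Part of these overlaps may come from a shared reference.

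BABA and SA differed in 70 genes, 36 higher and 34 lower under BABA. AT1G66760 stood at -2.84 under BABA and 1.47 under SA, a difference of -4.31 ± 0.33. The glycosyltransferase gene GT72B1 (-2.61 ± 0.48), the alkenal reductase gene AER (-2.58 ± 0.35), AT5G64250 (-2.45 ± 0.35) and COR15A (-2.42 ± 0.51) were lower under BABA. AT1G26380 (2.49 ± 0.54), AT2G18690 (2.03 ± 0.35), AT2G24600 (1.79 ± 0.36), AT1G78830 (1.78 ± 0.27) and AT5G17760 (1.67 ± 0.38) were higher, and the largest adjusted p of the 10 genes was 0.0020. The split was 4 higher and 33 lower in the deposited values, 4 and 85 after centring on TUA5, and 20 and 29 after quantile normalization.

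MeJA and ET, the jasmonate and ethylene treatments, differed in 38 genes, 15 higher and 23 lower under MeJA. AT3G28220 had the widest difference at 5.16 ± 0.45, followed by AT1G52000 at 3.47 ± 0.36, AT1G66100 at 2.79 ± 0.51, KIN2 at 2.08 ± 0.42 and AT1G54010 at 2.06 ± 0.32. AT5G64120 (-2.49 ± 0.37), AT4G38550 (-1.999 ± 0.29), AT4G36850 (-1.79 ± 0.47), AT2G39980 (-1.76 ± 0.29) and AT2G39400 (-1.75 ± 0.35) were lower under MeJA. The largest adjusted p of these 10 genes was 0.0091. After centring on TUA5 the split was 27 higher and 6 lower, and 22 genes passed without the 5 h conditions and 18 without 10 h. The mean of SA, INA and BTH differed from the mean of ET and MeJA in 115 genes, 51 higher and 64 lower. COR15A (2.65 ± 0.33), KIN2 (2.56 ± 0.27), AT5G51830 (2.22 ± 0.31), AT3G62550 (2.16 ± 0.33) and CCL (2.07 ± 0.28) had a higher mean over SA, INA and BTH. For AT3G62550 and CCL this came from SA (0.46 and 0.72) and INA (1.02 and 1.40), while BTH (-2.75 and -1.66) lay near ET (-2.21 and -1.90) and MeJA (-2.97 and -1.92). KIN2 under BTH (-2.05) likewise lay near MeJA (-2.30). AT3G28220 (-2.40 ± 0.29), AT1G52000 (-2.26 ± 0.24), AT3G21670 (-2.11 ± 0.36), AT2G26690 (-1.96 ± 0.17) and PYK10 (-1.85 ± 0.33) had a lower mean. MeJA carried the difference of AT3G28220 (3.12, against -2.43 under BTH and -2.04 under ET) and of AT1G52000 (2.59, against -1.15 under SA, -1.10 under INA, -1.98 under BTH and -0.89 under ET), and PYK10 lay at 1.31 under MeJA and -0.13 under ET. Under BTH and ET, AT3G21670 (0.05 and -0.45) and AT2G26690 (-0.24 and 0.22) did not pass the threshold. Both genes were lower under SA (-2.18 and -1.92) and INA (-2.93 and -2.26) and higher under MeJA (1.28 and 0.75). That split was 36 and 30 in the deposited values and 82 and 16 after centring on TUA5.

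Over time, late conditions (10 and 24 h) were compared with early ones (2 and 5 h) across all agents. The mean ratio of COR15A went from -1.45 early to -4.05 late, a difference of -2.60 ± 0.47. KIN2 (-2.30 ± 0.39), AT3G15450 (-1.81 ± 0.49), AT2G30600 (-1.80 ± 0.26) and COR47 (-1.56 ± 0.25) were lower late as well. AT2G25510 was higher late by 1.55 ± 0.23, ECS1 by 1.27 ± 0.21, the calmodulin-like gene AT2G41090 by 1.22 ± 0.22, AT5G64120 by 1.21 ± 0.22 and PPDK by 0.83 ± 0.21. The test called 45 genes, 16 higher and 29 lower late. The split was 4 and 12 in the deposited values and 31 and 11 after centring on TUA5, and the total was 13 without the 2 h conditions and 23 without 24 h. A difference between agents in the late minus early change passed the threshold in 0 of 180 genes (F-test in the same limma model), with 7 genes at an unadjusted p under 0.05. The late against early test counts agents at the same time as independent. If they shared untreated RNA at each time, which is not stated, the SEs above are too small. With whole times exchanged for all agents together, another pairing of the times gave 29 genes, against 45 for the real one.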

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

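The tests of centring, shared reference, dye offset and humidity, the repeats under other centrings, the simulation and the splits with matched times or whole agents were chosen after the results were seen. Several genes moved in opposite directions under agents that are compared with each other, with the difference itself past the threshold. This was so for 12 genes between BTH and SA, for 7 between BTH and INA, for 6 between BABA and SA, for 3 between MeJA and ET and for 1 between INA and SA. The 3 genes of MeJA and ET were AT3G28220 (3.12 and -2.04), AT1G52000 (2.59 and -0.89) and AT1G66100 (1.67 and -1.11). The gene of INA and SA was AT5G61590 (0.70 and -0.38). These counts changed with the centring: in the same order they were 3, 3, 6, 1 and 0 in the deposited values and 5, 6, 9, 3 and 0 after centring on TUA5. Of the genes above, 2, 3, 2, 1 and 0 were among the former and 1, 2, 2, 1 and 0 among the latter. Late and early times differed in 45 genes.

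Unnamed spots outside the main measurement passed the threshold about as often as named spots. Among 872 unnamed spots with enough values, 835 passed the threshold under at least 1 agent, which is 95.8%, against 96.6% of the named spots. Shares this high do not tell a response to an agent from an offset of dye or centring.

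KIN2, COR15A and COR47 had a mean log2 difference of -2.54 ± 0.22 between ET, MeJA and BTH on one side and SA and INA on the other, a grouping chosen after the values were seen. COR15A under BTH did not differ past the threshold from SA (-1.23, limma, adjusted p = 0.058) or INA (-1.02, adjusted p = 0.13), and under BABA, which is outside the grouping, it was lower than under SA (-2.42, adjusted p = 0.0013). Centring of the arrays as the cause of the mean difference is argued against, since the value closest to 0 over 5 centrings or scalings was -2.07 ± 0.27. A reference shared by all agents at each time cancels between agents, so by design it cannot give the difference, and the values are no test of it. In the grouping, which was chosen from these values, 3 of 3 genes lay more than 2 SE below 0. Each also differed over all 6 agents without a grouping (F-test in the limma model, largest adjusted p = 5.25e-06). Of all 180 genes tested, 155 differed between agents in this way. Untreated plants that differed between the experiments of the agents and a response to the agents remain open and were not tested.

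The same 3 genes, which are among the 5 lowest in late minus early, had values below 0 in 18 of 18 combinations of gene and agent. If the untreated RNA was shared by the agents at each time, which is not stated, these values share its deviations. In simulations with no change, 18 of 18 fell below 0 in 1.47% of 10000 runs with a shared reference and in 0.02% with separate ones, for genes not chosen by their values. There too the reference and each agent were drawn with equal variance. The correlation between the genes came from residuals after the time terms, which take up deviations common to all agents at a time. These shares therefore set no bound on what a shared reference could give. A change of these genes in the untreated plants over time and high humidity after spraying, without a mock-sprayed control, both remain open. Humidity and treatment cannot be told apart, because every treated plant had both.

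Of the genes tested, 8 were higher and 9 lower under all 6 agents. A constant dye offset as the whole cause is argued against for 16 of these 17 genes, which differed between agents (15 genes) or between late and early times (4 genes). Differences between agents were found for 155 of all 180 genes tested, so they are not particular to these 17 genes. For the remaining 1 gene, AT1G07440, a constant dye offset cannot be told apart from an equal response, because no difference was detected. A dye offset beside a response stays open for all 17 genes. High humidity after spraying, without a mock-sprayed control, was common to all 6 agents, and the untreated RNA may have been. Both stay open as a cause or part of it for all 17 genes and were not tested. The pattern itself depended on the centring, with 14 genes higher and 1 lower under all 6 agents in the deposited values and 38 and 0 after centring on TUA5. The 8 higher genes were among those called under both, and of the 9 lower genes 1 and 0 were.

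Other splits of the conditions gave fewer genes than the real grouping in every comparison tried. Where a split mixes conditions that differ, their difference enters the residual, which lowers its count in advance. The splits therefore do not decide whether chance gave the real counts. For BTH and SA the real split gave 73 genes and the highest of the other 34 gave 10, so that 1 of 35 splits was as large. This was also 1 of 35 for BTH and INA (61 against 2), BABA and SA (70 against 13), MeJA and ET (38 against 8) and INA and SA (12 against 10). Most of these splits mix the times unevenly. Swaps within times leave 8 splits, too few for a share under 0.05, and the highest of the others gave 1 for BTH and SA, 0 for BTH and INA, 12 for BABA and SA, 5 for MeJA and ET and 0 for INA and SA. For late against early times, 1 of 100 splits drawn within agents was as large (45 against 12). With times exchanged for all agents together there are 3 splits, again too few, and the highest of the others gave 29. For SA, INA and BTH against ET and MeJA, 1 of 100 splits was as large (115 against 17), and likewise 1 of 100 with agents exchanged within times (115 against 26). These splits break up the 4 times of an agent. With whole agents exchanged there are 10 splits, too few for a share under 0.05, and the highest of the others, SA and INA against BTH, ET and MeJA, gave 105.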

How the results depend on the processing

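Centring on TUA5 and leaving out the BABA arrays were chosen after seeing the data. Most of the 201 named gene results were picked as the highest and lowest calls in these same data, so how well they held does not extend to other calls. Of these 201 results, 162 kept their direction and their side of the threshold under every alternative run for them. Over 4415 values, 4259 did so, 152 kept the direction and lost the call, and 4 reversed. All 4 reversed after centring on TUA5: COR15A (0.0285) and COR47 (0.27) under SA, and EIN3 under BTH (0.54, past the threshold in the opposite direction) and MeJA (0.35). There are no intensities, so signal over background cannot be weighed. Counts of genes past the threshold that moved by over 1.5 times are given by setting, and the cause was not tested unless stated.

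In the deposited values, INA against SA gave 5, BTH against SA 48, BTH against INA 26, BABA against SA 37, MeJA against ET 22, the SA-type agents against ET and MeJA 66 and late against early 16. Scale normalization gave 6 for INA against SA and 42 for BABA against SA. After centring on TUA5, MeJA gave 127 and INA against SA 6. Genes with a value on every array are fewer, and gave 87 for SA, 71 for INA, 70 for BTH, 79 for BABA, 64 for ET, 51 for MeJA, 5 for INA against SA, 44 for BTH against SA, 41 for BABA against SA, 22 for MeJA against ET and 72 for the SA-type agents against ET and MeJA. Single spots, named or not, are more than genes, and gave 881 for SA, 802 for INA, 766 for BTH, 846 for BABA, 674 for ET, 648 for MeJA, 118 for INA against SA, 506 for BTH against SA, 488 for BTH against INA, 426 for BABA against SA, 211 for MeJA against ET, 701 for the SA-type agents against ET and MeJA and 143 for late against early.

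Without a time term, INA against SA gave 1, BTH against SA 45, BTH against INA 20, BABA against SA 33 and MeJA against ET 11. With the conditions compared alone and no time term, so fewer samples, INA gave 70, BABA 79, ET 59, MeJA 45, INA against SA 0, BTH against SA 41, BTH against INA 21, BABA against SA 21 and MeJA against ET 13. A minimum fold of 1.5, a stricter test, gave 71 for SA, 42 for INA, 49 for BTH, 73 for BABA, 38 for ET, 29 for MeJA, 0 for INA against SA, 31 for BTH against SA, 18 for BTH against INA, 18 for BABA against SA, 14 for MeJA against ET and 38 for the SA-type agents against ET and MeJA. Moving the doubtful INA array to 2 h gave 26 for INA against SA. The additive model for 24 h against 2 h gave 76 genes in place of 45.

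Leaving out a time or a repeat array gave 115 to 129 for SA, 85 to 118 for INA, 91 to 106 for BTH, 103 to 126 for BABA, 73 to 100 for ET, 68 to 84 for MeJA, 0 to 19 for INA against SA, 59 to 72 for BTH against SA, 39 to 57 for BTH against INA, 47 to 70 for BABA against SA, 18 to 38 for MeJA against ET, 88 to 111 for the SA-type agents against ET and MeJA, 13 to 50 for late against early and 3 to 4 for the gene list tests. Differences between agents in the late minus early change numbered 0 under each alternative run, with 3 to 10 genes at an unadjusted p under 0.05 and 43 single spots.

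With the 27 arrays kept separate and the replicate number as a block, no count moved by over 1.5 times. The blocked counts were 131 for SA, 112 for INA, 112 for BTH, 120 for BABA, 98 for ET, 83 for MeJA, 9 for INA against SA, 73 for BTH against SA, 70 for BTH against INA, 69 for BABA against SA, 39 for MeJA against ET, 112 for the SA-type agents against ET and MeJA, 3 for the gene list tests, 44 for late against early and 0 for the difference between agents. Without the block INA against SA gave 24.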

Other observations

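The lists in this part were drawn up after the gene names were seen, and the tests were chosen after the results were seen. Of 3 tested genes for berberine bridge enzyme-like oxidases, 2 were higher under SA, 2 under INA, 2 under BTH, 3 under BABA, 3 under ET and 0 under MeJA. Of 6 tested genes for NB-ARC and TIR proteins, which are homologs of resistance genes, 5 were lower under SA, INA, BTH and BABA and 2 under ET and MeJA. After centring on TUA5, 1 was lower under SA, 0 under INA, 1 under BTH and 4 under BABA, and the median of the list turned from -0.77 to 0.10 under INA, from -1.14 to 0.23 under BTH and from -0.52 to 0.34 under MeJA. All 3 tested genes of ER bodies and associated lectins were higher under MeJA, while 2 were lower under SA, INA and BTH, 1 was higher and 1 lower under BABA, and 0 passed under ET. The MeJA count stayed at 3 after centring on TUA5, when 0 were lower under SA, INA and BTH and 2, 1 and 2 were higher. Of 4 class III peroxidase genes, 3 were higher and 1 lower under SA, INA and BABA, 2 higher and 1 lower under BTH and ET, and 2 higher under MeJA, and after centring on TUA5 0 were lower under SA and INA and 1 under BABA. Of 4 UDP-glycosyltransferase genes, 4 were higher under SA, 3 under INA, 2 under BTH and 1 under MeJA, and 2 were higher and 1 lower under BABA and ET. Of 4 EF-hand genes, 3 were higher under BABA, 2 under ET and 1 under INA and BTH, with 2 higher and 1 lower under SA and 1 higher and 1 lower under MeJA. After centring on TUA5 the lower calls were lost for UDP-glycosyltransferases under ET and for EF-hand genes under SA and MeJA. Of 3 genes of amino acid catabolism, 2 were higher under SA, BTH and ET and 1 under INA, BABA and MeJA. The 1 tested gene of the alkenal reductase family was higher under SA and INA and lower under BABA and ET, and the lower calls were lost after centring on TUA5. None of the 42 list-by-agent tests against the other genes (camera) passed the threshold, with 8 at an unadjusted p under 0.05. With an estimated correlation these counts were 0 and 4. The closest were berberine bridge enzyme-like oxidases under INA and BABA and ER bodies under MeJA, each with an adjusted p of 0.094.

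The genes higher under all 6 agents were AT2G18690, AT5G64120, AT2G41410, AT5G14120, FDH, AT4G34180, AT4G37520 and UGT72E1. Those lower under all 6 were COR15A, AT1G29660, FUG1, AT2G45820, AT3G61260, AT1G73390, AT3G20820, AT1G07440 and AT2G25450. Of these 9 lower genes, 0 were lower under all 6 agents after centring on TUA5.

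BTH is used as an analog of SA, and its means correlated across genes more with ET (0.752) than with SA (0.600). A hypothesis is that the response to BTH was closer to that to ET at every time. Time by time over the tested genes, the correlation with ET exceeded that with SA at 3 of 4 times. It was 0.734 against 0.616 at 5 h, 0.771 against 0.625 at 10 h and 0.767 against 0.524 at 24 h. At 2 h it was 0.561 against 0.591 over the tested genes, but 0.563 against 0.536 over all spots of the arrays. The order at 2 h thus depended on the spots used, and the spread of these correlations was not estimated. The same 4 times gave the means that prompted the hypothesis, so they are no independent test of it. They do not decide how close the responses were. Untreated RNA shared between the BTH and ET arrays might give a correlation with ET above that with SA.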
